A study of Mus musculus with 2 samples.

How the data were processed

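Th2 cells had been cultured from naive CD4 T cells of mouse spleen and loaded on droplet-based 3' single-cell libraries, of which 1 came from Usp7 wild-type and 1 from Usp7 knockout cells. Groups were taken from the genotype given for each library. Live cells had been sorted before loading, per the labels' protocols. The deposited matrices hold counts of UMIs per gene and barcode, whole numbers that are not normalized. Per the submitters' processing notes, Cell Ranger 6.0.0 and the build mm10 were used, while the header of the matrices names software version 3.0.2, per the file headers. The counting of reads shared between genes and the annotation release are not given in the sources used here. The features were 31053 genes, of which 36 shared a symbol with an earlier one. The smallest barcode held 500 UMIs in each library.

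Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, which left out 42.3% of wild-type and 24.7% of knockout barcodes. Doublets were called with Scrublet in scanpy 1.11.5 (expected rate 0.06). It marked 2 cells in each library, under the 0.5% set as the least a working caller should mark, so cells above the 98th percentile of UMIs (103 wild-type and 89 knockout cells) were removed in its place. Doublets of ordinary depth therefore remain. The alternative called doublets kept restored the cells above that percentile, which need not be doublets.

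UMIs were summed over the kept cells of each library and divided by the total (CPM). The log2 ratio is that of CPM plus 1 in the knockout over the wild-type, and genes entered with at least 10 CPM in a library. A pseudocount of 1 understates the ratios of low genes. Ratios without pseudocount carry exact conditional binomial 95% intervals, and shares of cells exact binomial ones. Differences were called by size, 2-fold for all genes and 1.5-fold for members of a list. For a CPM of 0 the limit is 3 counts. The ratio of Prf1 and Gzmc inside cluster 4 was also taken over 10000 draws of its cells, chosen after seeing the data, since single cells held up to 170 of these UMIs. With 1 library per genotype no p-value was computed.

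The lists of genes (36) and of cell type markers (19), the filters, the rule for named genes and the first set of alternatives were fixed before the data were examined. They were chosen with knowledge of published work on Usp7, Stat3 and granzymes in Th2 cells. A list median was placed among the medians of 10000 random lists of the same size, matched in 20 bins of expression (log2 of the mean CPM, where the plan said the mean of log2 CPM), if at least 4 members were measured. The text names Usp7, the 10 highest and 10 lowest log2 ratios among genes of at least 25 CPM on the same side in every cluster with at least 100 cells per library (predicted, mitochondrial, ribosomal protein and receptor segment genes left out), the members of at least 5 CPM of the Th2 cytokine, granzyme and series title lists, and the 2 highest and 2 lowest members of the other lists, as examples, and not every gene under this rule is printed. Genes named outside this rule are said to be chosen after their values were seen, or belong to the genes fixed for shares of cells and background.

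For shares of positive cells and phases, cells were thinned to 1000 UMIs, the 10th percentile in the library where it was lower (1235 in the knockout and 1292 in the wild-type), rounded down to a multiple of 500. Cells were clustered jointly on log-normalised counts with 2000 variable genes, 30 principal components, 20 exact nearest neighbours and Leiden resolution 0.6, without integration. Phases came from the S and G2M lists. Gene positions came from GENCODE M21 on GRCm38, the assembly of mm10, where 31011 of the 31053 gene IDs were found. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

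The ratios were tested on simulated data with the real means and totals. Of 50 genes each, true folds of 0.25, 0.5, 2 and 4 gave median log2 ratios of -1.90, -0.97, 1.00 and 1.97, and the intervals held the truth for 94%, 94%, 94% and 98% of them. Among 7359 genes without a difference, 0% were called 2-fold. Counts were drawn as Poisson, with no spread between cells or libraries beyond counting. This share therefore does not give the rate of false 2-fold calls in the real libraries. The known shift in the total made by the changed genes was added back to the recovered ratios. Of 400 random lists 7% lay outside the central 95%. Genes were simulated independently, so this does not cover lists whose members vary together.

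Alternatives covered scaling (median-of-ratios, TMM, a total without mitochondrial and ribosomal protein genes), the mean over cells in place of sums, thresholds of 2 and 50 CPM, a pseudocount of 5, other cell filters, clusters weighted alike, no cycling cluster, other thinning, other clusterings and list members held by another list. Added after seeing the data were leaving out cells under 1% mitochondrial UMIs, clusters 4 and 6, or clusters 2 and 4, removing the trend with transcript length and GC (cubic in both), a stricter ribosomal protein list, and the granzyme list without Gzmd, Gzme, Gzmf and Gzmg. Random lists numbered 1000 for each alternative. Each alternative applied its CPM minimum anew, so the measured members of a list could differ between alternatives. Inside clusters the members were those of the main setting. For Prf1 and Gzmc inside and outside cluster 4, chosen after seeing the data, cells were resampled 10000 times within each library, and the central 95% of the ratios was taken. Median-of-ratios and TMM factors were own code. T cell receptor sequences, splicing and the other genotypes named in the series design were not analysed here.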

Results

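Single-cell transcriptomes were collected from Th2 cells, the helper T cells that make interleukins such as Il4, Il5 and Il13. The cells had been differentiated in culture from splenic naive CD4 T cells of mice, with Il2 and Il4 in the medium. The libraries formed 2 groups, Usp7 wild-type and Usp7 knockout, with 1 library in each. The wild-type file held 8899 barcodes with 15637344 UMIs and the knockout file 5932 barcodes with 12142360 UMIs. After the cell filter 5035 wild-type cells with 12026656 UMIs and 4376 knockout cells with 10346525 UMIs remained. The median cell held 2176 UMIs and 1018 genes in the wild-type and 2055.5 UMIs and 1031.5 genes in the knockout. Because no library was repeated, no test was possible and no difference had a replicate check. Values are set side by side, and the 95% intervals (exact, Clopper-Pearson) cover counting error only.

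The comparison addressed how Th2 cells labelled Usp7 knockout differ from wild-type Th2 cells. Usp7, a deubiquitinase (ENSMUSG00000022710, GRCm38 chromosome 16, 8689595 to 8792308, minus strand), was counted at 68.8 CPM in the wild-type and 39.1 CPM in the knockout. Its ratio was 0.569 (0.504 to 0.642), a log2 ratio of -0.80, and it was lower in each of the 5 clusters with at least 100 cells in both libraries. With all barcodes its log2 ratio was -0.60. The labels do not state which exon was deleted, and 3' tags outside a deleted part check nothing, so the remaining Usp7 tags say nothing about the protein.

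The knockout library held more of Il10, Epas1, Lif, P2rx7 and the S phase genes than the wild-type library, and less of Gzma, Prf1, C3, Gipr, Malt1 and the glycolysis and hypoxia genes. Of 7886 genes with at least 10 CPM in a library, 180 were at least 2-fold higher and 115 at least 2-fold lower in the knockout. The log2 ratios of all these genes had a median of 0.11, with 5th and 95th percentiles of -0.65 and 0.79. Scaling moved this balance. Of the genes beyond 2-fold, 61.0% were higher in the knockout with CPM, 39.4% with median-of-ratios factors and 43.2% with TMM factors. The median of all genes was then -0.029 and -0.0094, a shift of -0.14 and -0.12. List medians are therefore given beside those of random lists of the same expression level. Genes of a random list are unrelated, while members of a gene list can vary together. A percentile therefore describes these 2 libraries and is not a test.

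Among genes of at least 25 CPM that lay on the same side in all 5 clusters, Nrgn, a calmodulin-binding protein, had the highest log2 ratio, 3.36, with 2.33 CPM in the wild-type and 33.2 CPM in the knockout. It was followed by the histone gene Hist1h2bc at 2.70, the ATP-gated channel gene P2rx7 at 2.67, and the transcription factor gene Fos at 2.04. P2rx7 was at 5.99 and 43.4 CPM, a ratio of 7.25 (5.64 to 9.43). Ctnnbip1 (1.97), Lurap1 (1.89), Tmem238 (1.74) and Vamp5 (1.64) were also among the 10 highest. With a pseudocount of 5 the log2 ratio of Nrgn was 2.38 and that of Hist1h2bc 2.10. The cytokine gene Lif, also among them, was at 43.1 and 146 CPM (3.40-fold).

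At the other end, the complement gene C3 was at 112 CPM in the wild-type and 20.1 CPM in the knockout, a log2 ratio of -2.42. Gipr, the receptor of the gut hormone GIP, was at 43.1 and 7.35 CPM (log2 ratio -2.40). Selenbp1 was at 221 and 66.3 CPM (3.33-fold lower), and Malt1, a protease of antigen receptor signalling, at 101 and 30.5 CPM (3.31-fold lower). Fam183b (-1.91), Gpr141 (-1.89), Spp1, encoding osteopontin (-1.69), the long non-coding RNA gene AC160336.1 (-1.68) and the NK receptor gene Klra7 (-1.67) were also among the 10 lowest. The lowest value of all, -3.17 for the airway secretoglobin gene Scgb1a1, rested on a single barcode that held 854 of its 1038 wild-type UMIs. Without it the ratio was 0.568 (0.437 to 0.735). The log2 ratios were -1.79 for C3, -1.41 for Gipr, -1.08 for Selenbp1 and -0.91 for Spp1 with clusters weighted alike. That of Klra7 was -0.67 without clusters 2 and 4 and -0.53 without clusters 4 and 6, alternatives chosen after seeing the data.

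**Figure D1:**
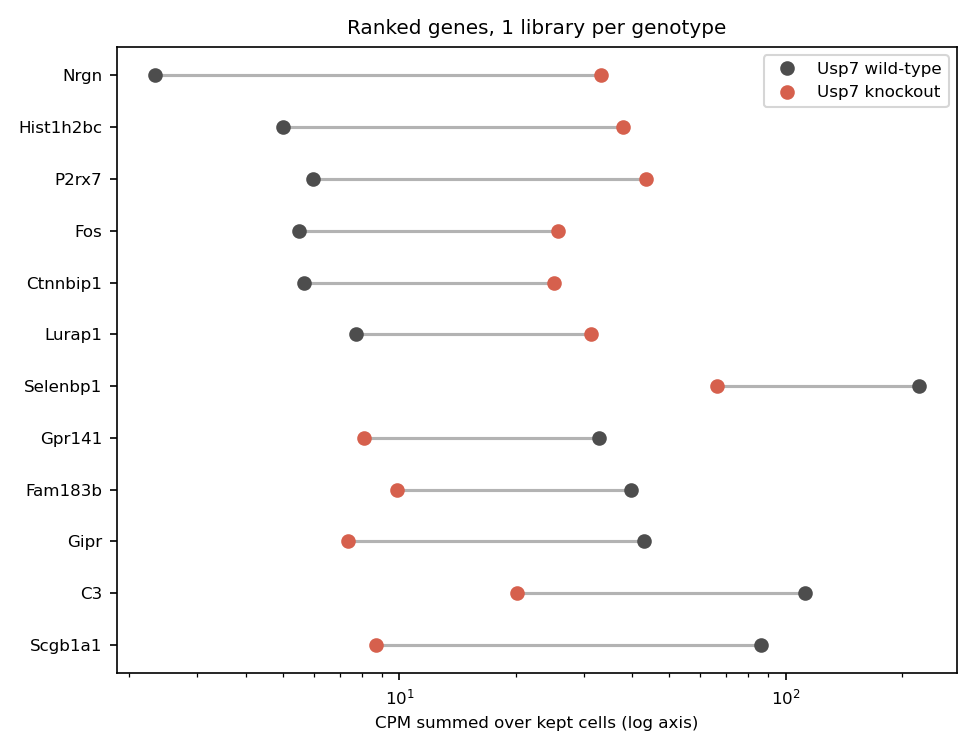
CPM in the Usp7 wild-type (grey) and Usp7 knockout (red) library, on a log axis, of the 6 genes with the highest and the 6 with the lowest log2 ratio under the ranking rule. Each point is 1 library and the line joins the pair, from Nrgn with a log2 ratio of 3.36 to Scgb1a1 with -3.17.

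Among the Th2 cytokines Il10 stood apart. It was at 113 CPM in the wild-type and 282 CPM in the knockout, a ratio of 2.49 (2.34 to 2.66), and higher in 5 of 5 clusters. Il4 (ratio 0.877, 0.756 to 1.02) and Il5 (0.950, 0.750 to 1.20) had intervals that included 1. Il13 (1.13, 1.01 to 1.27), Penk (1.13, 1.01 to 1.27) and Il24 (1.38, 1.34 to 1.42) had ratios above 1 that fell short of the 1.5-fold call. These intervals treat UMIs as independent, also where several come from 1 cell, so they are too narrow for genes whose UMIs sit together. Inside clusters Il13 was higher in 5 of 5 and Il5 in 4 of 5, with ratios from 1.15 to 1.62 for Il5 in those 4, 0.801 in cluster 4, and intervals that included 1. With all barcodes the log2 ratio of Il13 was -0.14, and with clusters weighted alike that of Il5 was 0.36. Tnfsf11 was low in both libraries, at 1.33 and 6.67 CPM. Of the 6 measured members of the list, 1 was at least 1.5-fold higher and 0 lower, and the median log2 ratio of 0.18 lay at the 69.8th percentile of 10000 random lists. In clusters 1 to 5 the median was 0.24, 0.49, 0.40, -0.00025 and 0.67, and with all barcodes -0.044. Gata3, the lineage-defining factor of Th2 cells, was at 257 CPM in the wild-type and 362 CPM in the knockout (ratio 1.41). Among the 23 Th2 factors and receptors 7 were higher and 2 lower, with a median of 0.15 (78.0th percentile). Gfi1 (2.05-fold higher) and Notch2 (1.88-fold higher) stood at one end and Maf (log2 ratio -0.61) and Bhlhe40 (-0.61) at the other, which with clusters weighted alike were at -0.26 and -0.42.

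The granzymes and their partners split. Gzma was at 3445 CPM in the wild-type and 1397 CPM in the knockout (2.47-fold lower), Gzmc at 133 and 54.3 CPM (2.45-fold lower), and the pore-forming perforin gene Prf1 at 124 and 39.8 CPM (3.12-fold lower). Gzmb was nearly level at 2958 and 3100 CPM, a ratio of 1.05 (1.03 to 1.06), and its direction flipped with scaling, from 0.067 to -0.071 on the log2 scale. Serpinb6b (log2 ratio -1.57) and Serpinb9 (-0.59), inhibitors of serine proteases, were lower. F2r, the thrombin receptor Par-1, was 1.62-fold higher (1.45 to 1.81), F2rl2 1.32-fold higher and F2rl1 lower (ratio 0.683, 0.497 to 0.932), and Srgn, the proteoglycan of cytotoxic granules, 1.26-fold higher. Of 13 measured members 5 were higher and 5 lower, and the median of 0.34 lay at the 96.3rd percentile. This sign rested on Gzmd, Gzme, Gzmf and Gzmg, the 4 highest members. Leaving them out, a choice made after seeing the data that by itself lowers the median, gave -0.59. The median of the whole list was -0.23 with all barcodes and -0.34 with doublets kept, and in clusters 1 to 5 it was -0.22, -0.48, 0.21, 0.14 and 0.

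Gzma turned direction when clusters were given equal weight in both libraries, with a log2 ratio of 0.10 in place of -1.30. Inside clusters it was lower in 4 of 5, with ratios of 1.51, 0.489, 0.842, 0.834 and 0.687 in clusters 1 to 5. Gzmd (1.51), Gzme (1.87), Gzmf (2.80) and Gzmg (1.62) had positive log2 ratios that rested on few cells. Their UMIs lay in 34 wild-type and 28 knockout cells, and 2 knockout cells held 55.5% of the 1121 knockout UMIs. Without clusters 4 and 6, an alternative chosen after seeing the data, the values were -0.10, -0.10, -0.28 and -0.21. Those of Gzmd, Gzme and Gzmg were 0.30, -0.14 and -0.32 with all barcodes, and 0.054, -0.34 and -0.70 with doublets kept. Prf1 and Gzmc lay mainly in cluster 4, with 11.8% of their wild-type UMIs outside it. Their joint ratio was 0.648 inside cluster 4 (0.397 to 0.997 over resampled cells) and 0.527 outside it (0.327 to 0.816). The log2 ratio of Prf1, -1.62 in all cells, was -0.83 with clusters weighted alike and -0.60 without clusters 2 and 4. Gzmb was at 0.70, Serpinb9 at -0.17 and F2r at 0.46 with clusters weighted alike.

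**Figure D2:**
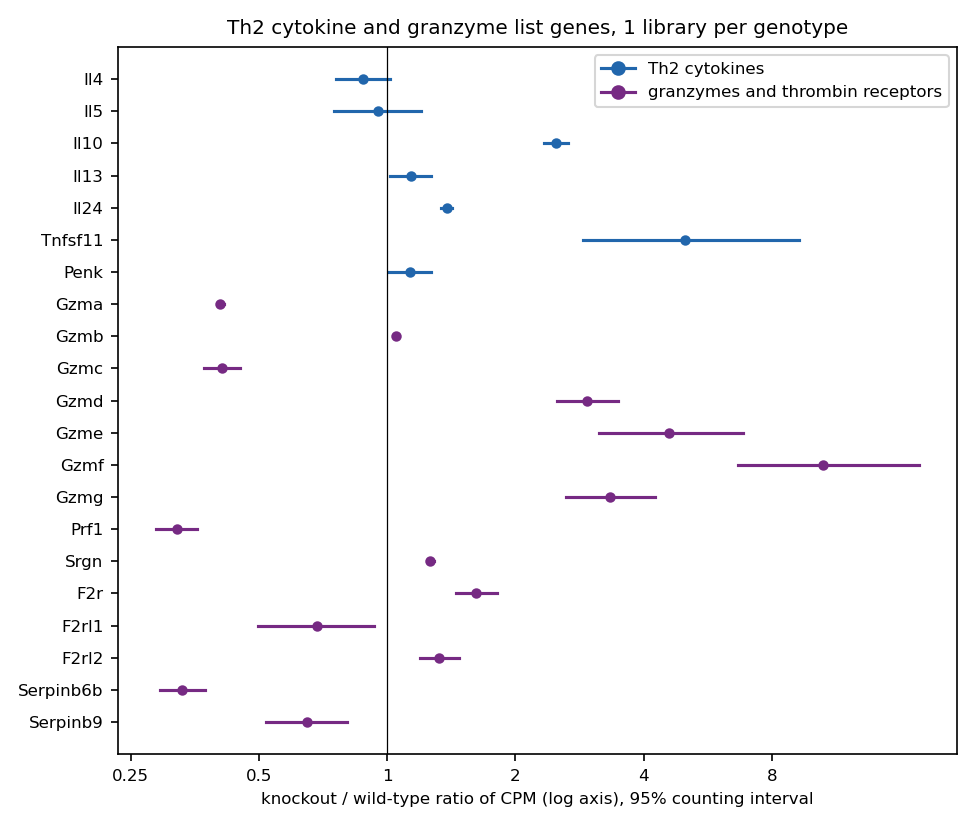
Knockout to wild-type ratio of CPM, on a log axis, of the Th2 cytokines (blue) and of the granzymes and thrombin receptors (purple), with 1 library per genotype. Points are ratios and lines their 95% counting intervals. Il10 lies at 2.49 and Prf1 at 0.321, while Il5 lies at 0.950 with an interval that includes 1.

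Shares of positive cells were read after each cell was thinned to 1000 UMIs, a depth that left out 0 wild-type and 0 knockout cells. Il10 UMIs were found in 10.2% of wild-type cells (9.35 to 11.04) and 21.4% of knockout cells (20.2 to 22.6). Gata3 was found in 22.1% and 31.1%, F2r in 4.41% and 7.998%, and Usp7 in 6.73% and 3.84%. Gzma UMIs were found in 51.6% of wild-type and 19.6% of knockout cells. For Gzmb the share was 60.5% and 43.9%, and 40.2% and 32.6% at 2 or more UMIs, so fewer knockout cells were positive. Its CPM was nearly level, and a share does not measure a summed level, so no order of its level is read from the share. Il5 was found in 1.39% (1.09 to 1.75) and 0.937% (0.673 to 1.27), Il4 in 3.34% and 3.47%, Il13 in 3.42% and 3.88%, Stat3 in 10.7% and 9.73%, and Ifng in 0.258% and 0.160%, each with overlapping intervals.

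Without thinning, the shares in the wild-type and the knockout were 19.6% and 35.2% for Il10, 41.1% and 51.8% for Gata3, 65.6% and 26.3% for Gzma and 73.4% and 52.7% for Gzmb. They were 2.46% and 1.99% for Il5, 7.77% and 6.90% for Il4, 6.43% and 6.42% for Il13, 22.6% and 20.7% for Stat3, and 0.675% and 0.434% for Ifng. For F2r they were 9.95% and 14.8%, and for Usp7 14.7% and 8.55%. No cluster was named as another lineage, so no background share could be read for the genes above. Genes of other cells, which do not measure the background of abundant genes such as Gzma, were nearly absent at the same depth. Cd79a of B cells was found in 0.0199% of wild-type and 0 of 4376 knockout cells, Lyz2 of macrophages in 0.0199% and 0.0457%, and the haemoglobin gene Hbb-bs in 0 of 5035 and 0 of 4376 cells, which allows up to 0.0732% and 0.0843%.

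Il5 and granzymes were also read in the same cells. Among wild-type cells with a Gzma or Gzmb UMI, 1.51% (58 of 3848, 1.15 to 1.94) had an Il5 UMI, against 1.01% (12 of 1187, 0.523 to 1.76) of those without. In the knockout the shares were 1.47% (33 of 2243, 1.01 to 2.06) and 0.375% (8 of 2133, 0.162 to 0.738). Conversely, 82.9% of wild-type and 80.5% of knockout cells with Il5 had a granzyme UMI, against 76.3% and 51.0% of cells without Il5. Unthinned, Il5 was found in 2.63% of granzyme cells and 1.28% of the others in the wild-type, and in 2.68% and 0.929% in the knockout.

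Genes of the hypoxia response and of glycolysis were lower in the knockout. The hypoxia response list had a median log2 ratio of -0.59, below all 10000 random lists (percentile 0), with 12 of 24 members at least 1.5-fold lower and 0 higher. The collagen hydroxylase gene P4ha2 was at 74.7 and 32.4 CPM (2.31-fold lower) and the oxidase gene Ero1l at 1168 and 517 CPM (2.26-fold lower), while the highest ratios were those of Kdm3a (1.30) and Ankrd37 (1.21). Ero1l had a log2 ratio of -0.40 in place of -1.18 with clusters weighted alike, short of 1.5-fold, and Ldhb one of 0.25 in place of 0.86. Glycolysis, which shared 0 measured members with the hypoxia list, had a median of -0.55 (percentile 0), with 10 of 21 members lower and 1 higher. Gapdh was at 8470 CPM in the wild-type and 4240 CPM in the knockout, Aldoa at 5223 and 2769 CPM, and Ldhb at 37.5 and 68.8 CPM. With clusters weighted alike the hypoxia median was -0.29 and the glycolysis median -0.30, and inside clusters 1 to 5 the hypoxia median was -0.11, -0.57, -0.34, -0.46 and -0.31 and the glycolysis median -0.23, -0.47, -0.36, -0.32 and -0.44.

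The list called series title genes, fixed beforehand, includes regulators of the oxygen response, and its members need not all be named in the title. Epas1, encoding HIF-2 alpha, was at 65.4 CPM in the wild-type and 173 CPM in the knockout, a ratio of 2.65 (2.44 to 2.89), higher in 5 of 5 clusters. Hif1a was lower, at 630 and 434 CPM (ratio 0.688, 0.663 to 0.714), and Arnt, their shared partner, had a ratio of 0.858 (0.696 to 1.06). The myosin light chain genes Myl12a and Myl12b had ratios of 1.25 and 1.12 (log2 ratio of Myl12b -0.062 with clusters weighted alike), and Cd69, an early activation receptor, had a ratio of 0.603 (0.512 to 0.709), a log2 ratio of -0.70 that was -0.29 with clusters weighted alike. Myl9 had 0 UMIs in both libraries, which allows up to 0.249 CPM in the wild-type and 0.290 CPM in the knockout. The 6 measured members had a median of -0.022 (23.4th percentile), with 1 higher and 1 lower.

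S phase genes were higher in the knockout, with a median log2 ratio of 0.74, above all 10000 random lists (percentile 100). Of 42 members 31 were at least 1.5-fold higher and 0 lower, and in clusters 1 to 5 the median was 0.26, 0.34, 0.68, 0.56 and 0.92. The replication licensing gene Cdc6 was at 6.74 and 17.5 CPM (2.60-fold), and Tyms, the thymidylate synthase gene, at 41.8 and 94.5 CPM (2.26-fold). Blm and Ubr7 were level, with ratios of 1.04 each and a sign that flips with scaling. The G2M list had a median of 0.026 (9.63rd percentile), with 5 of 51 members higher, among them Anp32e (1.80-fold), and 2 lower, among them Gas2l3 (ratio 0.593), and its sign flips with scaling, to -0.10.

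Phase scores on cells of 1000 UMIs put 6.81% of wild-type cells (6.13 to 7.54) and 17.6% of knockout cells (16.5 to 18.8) in S phase, and 32.7% and 30.5% in G2M. Without thinning the S phase shares were 5.20% and 18.2% and the G2M shares 27.3% and 25.5%. Phases are ranges of a score, and 32.0% of wild-type and 31.1% of knockout cells lay within 0.05 of a boundary. Cluster 2, named cycling cell-like from all 7 of its fixed markers, held 16.5% of wild-type cells (15.5 to 17.6) and 18.5% of knockout cells (17.4 to 19.7). With cell cycle and sex-linked genes left out of the clustering, the cluster of that name held 13.6% and 5.48%, and an unnamed one 4.19% and 36.7%. The S phase genes Rrm2, Tyms and Mcm3 were among the top genes of the unnamed cluster, Rrm2 and Mcm3 being named after their values were seen. Cells were divided otherwise there, so no order is read from the share of the cycling cell-like cluster.

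The measured Th1 genes, 10 of the 21 listed, were lower in the knockout, with a median of -0.52 (0.02nd percentile) and 4 of 10 members lower, 1 higher. Tbx21, named after its values were seen, was at 2.16 CPM in the wild-type and 2.61 CPM in the knockout, and Ifng at 3.82 and 2.61 CPM. Both lay below the minimum of 10 CPM, so the median does not cover them. Eomes was at 14.5 and 4.54 CPM (3.18-fold lower) and Hopx at 37.9 and 18.6 CPM (2.04-fold lower), while Tnf was 1.86-fold higher. Eomes had a log2 ratio of -0.76 in place of -1.48 with clusters weighted alike and Tnf one of 0.26 in place of 0.82, and without clusters 2 and 4 that of Hopx was -0.47 in place of -0.99. Summed markers of cytotoxic cells were lower too, with a ratio of 0.427 (0.343 to 0.529) for NK cells and 0.642 (0.548 to 0.751) for CD8 T cells. Eomes belongs to the Th1 list and to both of these marker sets, so these are not separate results. Without Eomes the NK ratio was 0.561 (0.417 to 0.750). Eomes, at 14.5 and 4.54 CPM, was also a large part of the CD8 sum of 37.5 and 24.1 CPM. The CD8 ratio without it was not taken, so no lower level of the other CD8 markers is read from that sum. Of the CD8 markers, named after their values were seen, Cd8a had a ratio of 1.31 and Cd8b1 of 0.822. The gamma-delta T cell markers had a ratio of 1.27 (1.12 to 1.44) and the general T cell markers 0.989 (0.979 to 1.00). Cluster 4, in which all 8 Th1 markers were raised together with CD8, gamma-delta and NK markers, stayed unnamed and held 5.36% of wild-type and 2.58% of knockout cells. Without clusters 2 and 4, an alternative chosen after seeing the data, the Th1 median was 0.0014, while inside clusters 1 to 5 it was -0.29, -0.27, -0.42, -0.26 and -0.12. It also lay inside the central 95% of random lists from 50 CPM (-0.25), without clusters 4 and 6 (-0.020) and with clusters weighted alike (-0.19). Each alternative applied its CPM minimum anew, so its measured Th1 members could differ from the 10 used inside clusters. These medians are therefore not compared over the same genes.

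Treg genes had a median of -0.30 (0.55th percentile) although 4 of 11 were higher and 2 lower, so the median and the numbers of members differ in sign. Izumo1r (2.55-fold) and Tgfb1 (1.82-fold) were higher and Ikzf2 (log2 ratio -1.22) and Tnfrsf9 (-1.06) lower, and with clusters weighted alike Izumo1r had a log2 ratio of 0.70 and Tnfrsf9 of -0.35. Activation immediate early genes had a median of -0.20 (0.595th percentile), again with 4 higher, among them Fos (4.68-fold) and Jund (1.74-fold), and 3 lower, among them Irf8 and Cd69, of 17. In clusters 1 to 5 the Treg median was 0.021, -0.17, 0.12, -0.24 and 0.22 and the immediate early median 0.26, 0.26, -0.19, -0.098 and 0.19. Irf8 had a log2 ratio of -0.48 with clusters weighted alike. Both medians turned positive, to 0.084 and 0.18, when genes needed at least 50 CPM to enter. They lay inside the central 95% with clusters weighted alike (-0.026 and -0.021) and without clusters 4 and 6 (0.065 and -0.11). So did the Treg median from 2 CPM (-0.034) and without the cycling cluster (-0.21), and the immediate early median as a mean over cells (-0.10) and without clusters 2 and 4 (-0.0047). The measured members could differ between these alternatives.

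Targets of the tumour suppressor p53 were higher, with a median of 0.34 (99.0th percentile) and 10 of 25 members higher, 0 lower. The adaptor gene Phlda3 was at 98.5 and 208 CPM (2.11-fold) and the cell death gene Bax at 322 and 653 CPM (2.03-fold), while the lowest ratios were those of Rrm2b (0.702) and Fas (0.719). Phlda3 had a log2 ratio of 0.47 in place of 1.07 with clusters weighted alike. Cdkn1a, named after its values were seen, was 1.62-fold higher. With clusters weighted alike, where the measured members could differ, the p53 median was -0.036, while inside clusters 1 to 5 it was 0.35, 0.16, -0.094, 0.31 and 0.40. It lay inside the central 95% of random lists there (8.70th percentile) and with all barcodes (93.3rd), doublets kept (96.8th) and at most 5% mitochondrial UMIs (93.9th). Proteasome genes had a median of 0.31 (99.8th percentile, 8 of 38 higher, 0 lower), led by Psme3 (1.88-fold) and Psmd6 (1.82-fold). Genes of MYC targets and ribosome biogenesis had a median of 0.32 (99.6th percentile), with 4 of 28 higher, among them Nolc1 (2.24-fold), and 1 lower, Npm1 (log2 ratio -0.74). This median lay inside the central 95% as a mean over cells (86.8th), from 50 CPM (89.1st), without the cycling cluster (93.7th) and with clusters weighted alike (0.10, 68.5th). In clusters 1 to 5 the proteasome median was 0.26, 0.28, 0.15, 0.28 and 0.46 and the MYC median 0.068, 0.31, -0.034, 0.28 and 0.31. Npm1 was at -0.58 and Psmd6 at 0.58 on the log2 scale with clusters weighted alike, short of 1.5-fold.

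Genes of ribosomal proteins had a median of -0.083 (0.075th percentile), with 8 of 93 lower, led by Rpl38 (ratio 0.577) and Rps29 (0.581), and 3 higher. The list was taken by symbol and included kinases and like-named genes, without which the median of 77 genes was -0.087. The median lay inside the central 95% with all barcodes (-0.013) and from 50 CPM (7.25th percentile), and in clusters 1 to 5 it was -0.091, -0.072, -0.075, 0.039 and -0.098. In all, 33 lists had enough members for a percentile, of which 6 lay below and 4 above the central 95% of random lists.

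**Figure D3:**
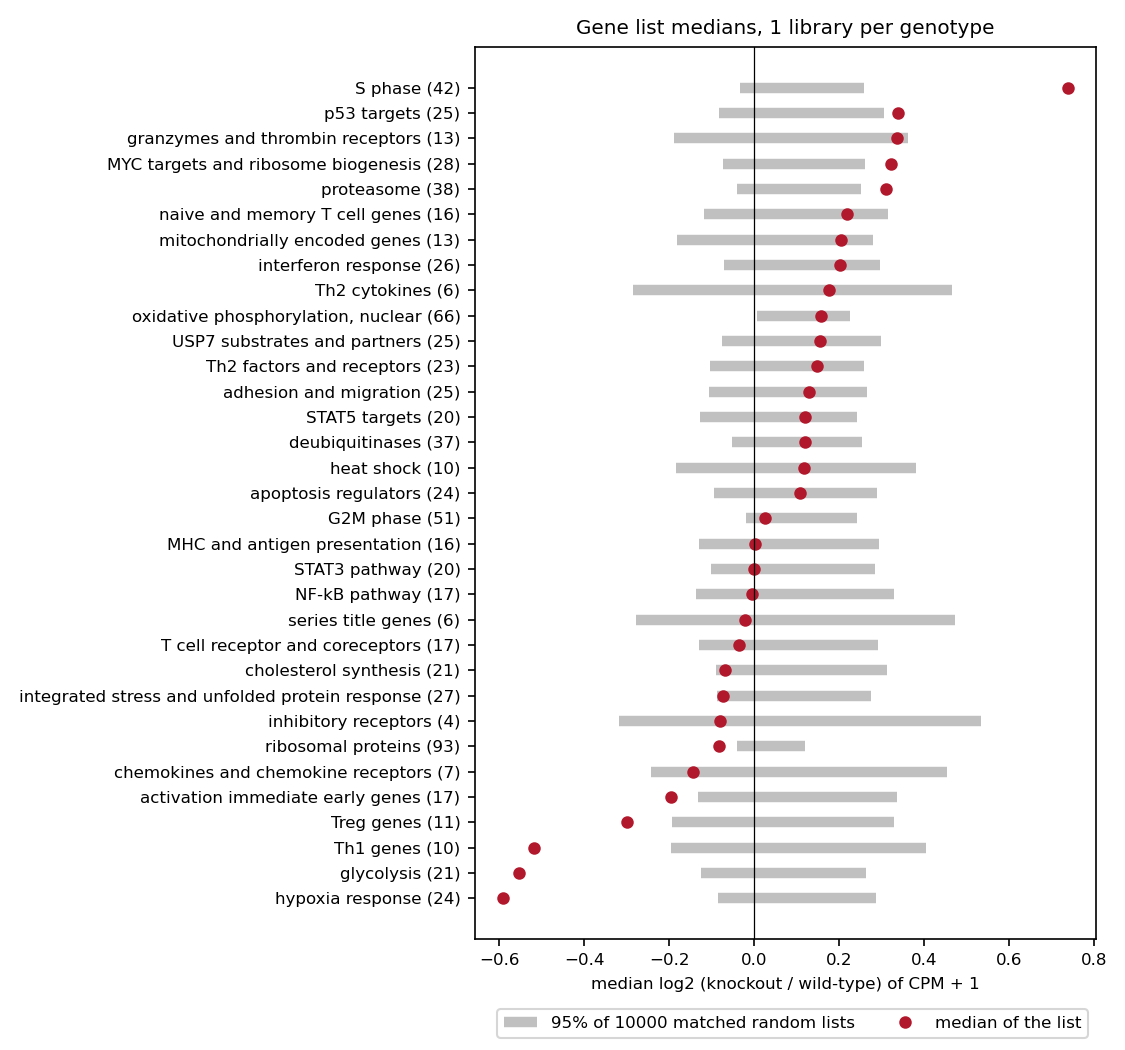
Median log2 ratio of knockout to wild-type (red points) of each gene list with at least 4 measured members, given in brackets, and the central 95% of the medians of 10000 random lists matched on expression (grey bars). The S phase list at 0.74 and the glycolysis and hypoxia response lists at -0.55 and -0.59 lie outside their grey bars.

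Joint clustering gave 6 clusters, and the 2 largest followed the libraries. Cluster 1 drew 89.2% of its cells from the wild-type library, and cluster 3 drew 14.6% from it, so neither can be told apart from its library, and their sizes are not compared. Clusters 5 and 6 held cells with little mitochondrial RNA, with a median of 0.113% and 0% of UMIs. Cells under 1% mitochondrial UMIs made up 18.1% of wild-type and 10.6% of knockout cells, and the median share of ribosomal protein UMIs was 21.5% and 18.9%.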

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

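The barcodes described here were looked at only after the data were seen, and no test was run on them. Barcodes that the cell filter left out entered only the alternative with all barcodes. Their median share of mitochondrial UMIs was 11.7% in the knockout, above the 10.2% in the wild-type, over 1467 and 3761 barcodes with a median of 686 and 700 UMIs. Among kept cells the medians were 3.88% and 3.16%.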

How the results depend on the processing

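Leaving out cells under 1% mitochondrial UMIs, clusters 4 and 6 or clusters 2 and 4, the removal of the trend with length and GC, the stricter ribosomal protein list, and the granzyme list without Gzmd, Gzme, Gzmf and Gzmg were chosen only after results were seen. The hypoxia response, glycolysis, S phase and proteasome medians lay outside the central 95% of random lists in 15 of 15 alternatives, the ribosomal protein median in 13, the Th1, p53 and MYC medians in 11 each, and the Treg and immediate early medians in 10 each. These numbers include the scalings, which apply a single factor to all genes of a library. A list and its random lists then shift nearly alike, so the scalings could hardly change a percentile. The hypoxia response median was -0.71 with TMM, -0.72 with median-of-ratios and -0.29 with clusters weighted alike. That weighting takes out any part of the difference held by the shares of clusters 1 and 3, drawn mainly from 1 library each. Whether they hold such a part was not tested. The S phase median was 0.63 with TMM, 0.61 with median-of-ratios, 0.67 as a mean over cells, 0.63 with a pseudocount of 5, 0.79 from 50 CPM, 0.47 with clusters weighted alike, 0.90 without the cycling cluster, 0.79 without cells under 1% mitochondrial UMIs, 0.98 without clusters 2 and 4 and 0.78 with the length and GC trend removed. Usp7 had a log2 ratio of -0.60 with all barcodes and -0.93 with median-of-ratios.

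The number of genes at least 2-fold higher was 307 from 2 CPM, 66 from 50 CPM, 117 with TMM, 106 with median-of-ratios, 102 with a pseudocount of 5 and 96 with clusters weighted alike. The number at least 2-fold lower was 204 from 2 CPM, 46 from 50 CPM, 69 with a pseudocount of 5 and 69 with clusters weighted alike. Thresholds and the pseudocount act by construction, and the cause was not tested for the others.

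Genes at least 1.5-fold apart and lists outside the central 95% turned direction as follows, and the cause was not tested. With clusters weighted alike Gzma was at 0.10 and the p53 median at -0.036. From 50 CPM the Treg and immediate early medians were 0.084 and 0.18. Without clusters 4 and 6 the Treg median was 0.065, Gzmd -0.10, Gzme -0.10, Gzmf -0.28 and Gzmg -0.21, and without clusters 2 and 4 the Th1 median was 0.0014. For the lists, the measured members could differ from those of the main setting. With all barcodes Gzme was at -0.14 and Gzmg at -0.32, and with doublets kept at -0.34 and -0.70. Of 2379 values of named genes under alternatives, 1891 stayed within the counting interval, 479 moved and 9, of 5 genes at least 1.5-fold apart, turned. The thresholds of 2 and 50 CPM cannot change the ratio of a gene. Their values are among the 1891 by construction, so that number overstates how stable the ratios were. Smaller ratios had the other sign in 32 values of 12 genes, among them Il13 at -0.14 with all barcodes, Il5 at 0.36 and Myl12b at -0.062 with clusters weighted alike, and Gzmb at -0.084 with all barcodes. Medians of the other lists had the other sign in 76 values of 20 lists, among them granzymes and thrombin receptors at -0.23 with all barcodes and -0.34 with doublets kept, and Th2 cytokines at -0.044 with all barcodes.

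In the wild-type and the knockout, Il5 was found in 2.46% and 1.99% of cells unthinned, 0.834% and 0.571% at 500 UMIs, and 0.139% and 0.0914% at 2 or more UMIs. Il5 among granzyme cells was 2.63% and 2.68% unthinned and 1.03% and 0.810% at 500 UMIs. The S phase share was 5.61% and 15.9% with all barcodes of at least 1000 UMIs, 16.2% in the knockout at 500 UMIs and 5.20% in the wild-type unthinned. The cycling cell-like share was 18.4% and 20.5% at resolution 0.3, 14.4% and 16.5% at resolution 1.0, 15.0% in the wild-type with another seed, and 13.6% and 5.48% without cell cycle and sex-linked genes.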

Other observations

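Chosen only after results were seen were the tests without clusters 2 and 4, those on cluster 4 and on cells holding the granzyme UMIs, and the alternatives that left out cells under 1% mitochondrial UMIs or removed the trend with length and GC, whose bounds were set before their values were known. Other lists lay within the range of random lists. Known substrates and partners of Usp7 had a median log2 ratio of 0.16 (66.4th percentile, 6 of 25 higher, 0 lower), with Mcm2 2.17-fold and Uhrf1 1.92-fold higher. Mcm2 and Uhrf1 also belong to the S phase list. The 19 members held by no other list had a median of 0.081, with 3 higher and 0 lower. RNA levels do not measure the substrate proteins. The deubiquitinases had a median of 0.12 (55.9th), with Usp1 1.57-fold higher and Stambp at a ratio of 0.548. The STAT3 pathway had a median of -0.00094 (17.7th), with Vim at a ratio of 0.612, and the STAT5 targets 0.12 (76.0th), with Lta 2.15-fold higher. Interferon response genes had a median of 0.20 (83.9th), with Slfn5 4.21-fold and Zbp1 2.47-fold higher and Slfn2 at a ratio of 0.567. Naive and memory T cell genes had a median of 0.22 (85.3rd), with Id3 2.84-fold and Ccr7 2.03-fold higher and Il7r at a ratio of 0.586. At their smallest over the alternatives, the log2 ratios were 0.34 for Ccr7 and -0.51 for Il7r, short of 1.5-fold. Chemokines and their receptors had a median of -0.14 (7.39th), with Ccr2 at a ratio of 0.415, and adhesion and migration genes 0.13 (68.8th), with Icam2 2.77-fold higher and Lgals3 at a ratio of 0.465. The log2 ratio of Lgals3 came to -0.48 under an alternative, short of 1.5-fold.

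Among metabolic and stress lists, nuclear genes of oxidative phosphorylation had a median of 0.16 (73.4th percentile), with Cycs 2.05-fold higher, and mitochondrially encoded genes 0.20 (91.2nd), with mt-Cytb 1.49-fold higher and mt-Atp8 at a ratio of 0.503. Cholesterol synthesis had a median of -0.068 (4.03rd), with Hmgcs1 at a ratio of 0.606, the integrated stress and unfolded protein response -0.073 (3.56th), with Sdf2l1 1.92-fold higher and Ddit3 at 0.582, and heat shock genes 0.12 (57.1st), with Hspa4 1.60-fold higher. Apoptosis regulators had a median of 0.11 (51.9th), the NF-kB pathway -0.0048 (18.7th), inhibitory receptors -0.080 (18.2nd), T cell receptor genes and coreceptors -0.036 (13.1st), and MHC and antigen presentation 0.0013 (22.9th), where H2-Ab1 was at 402 and 161 CPM. The medians of STAT5 targets, deubiquitinases, adhesion, heat shock, apoptosis and MHC genes turned sign with scaling. That of chemokines was 0.44 with the total without mitochondrial and ribosomal protein genes, where 8582 in place of 7886 genes passed the CPM minimum. It was 0.45 from 2 CPM, so a change in the measured members cannot be told apart from scaling there. Too few members for a percentile were measured of the Th17 list (2, median 0.20), of the genes around tamoxifen and Cre (3, median 0.22, Esr1 1.79-fold higher) and of the sex-linked list (Xist, at 546 and 552 CPM).

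Named after their values were seen, Gm42418 took 0.240% of wild-type and 0.698% of knockout UMIs. The barcode with 854 Scgb1a1 UMIs held 1811 UMIs in all, 32 of them from 7 of 15 other genes of lung epithelium, more than in any other kept cell, and 0 from Cd3e, Trac and Cd4. Summed markers of dendritic cells had a ratio of 0.432 (0.409 to 0.455), which was that of H2-Ab1, as the 7 others had a ratio of 1.29 (1.04 to 1.61). The ratio was 0.581 for macrophages (0.342 without Adgre1), 0.555 for neutrophils (0.281 without Mmp9), 0.581 for erythroid cells, 0.895 for interferon-responding cells, 1.10 for B cells and 1.10 for plasma cells (0.957 without Xbp1, and 1.16 for erythroid cells without Hbb-bt). Those of Th2 cells had a ratio of 1.47, Th1 cells 0.695, Treg cells 1.59 (carried by Izumo1r, with 0.592 for the 6 others), naive T cells 1.08, cycling cells 1.06, and mast cells or basophils 3.49 (1.52 to 8.98, from 8 and 24 UMIs, and 1.63 without Cpa3, with an interval that includes 1). The Th17 markers held 4 and 1 UMIs and those of platelets 4 and 4.

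The lower hypoxia response list, at -0.59, was weighed against droplets with little mitochondrial RNA, transcript properties and the cells of clusters 2 and 4. Without cells under 1% mitochondrial UMIs the median was -0.62, with the trend of transcript length and GC removed -0.58, and without clusters 2 and 4 also -0.58, all beyond the bound of -0.3, so none of these was the whole cause. With clusters weighted alike it was -0.29, short of that bound, so a part held by clusters 1 and 3, which follow the libraries, stays open. A culture or library difference other than genotype, such as oxygen or cell density, cannot be told apart from the knockout, since there was 1 library per genotype. Further libraries of each genotype, cultured alike, would decide whether genotype is the cause.

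The higher S phase list, at 0.74, had a median of 0.79 without cells under 1% mitochondrial UMIs and 0.78 with the trend of length and GC removed, both beyond the bound of 0.4, which argues against either as the whole cause. It was 0.90 without the cycling cluster, so the cells of that cluster were not needed for it. S phase cells placed in other clusters stayed in, so a larger share of S phase cells in the knockout stays open as the whole pattern. A culture or library difference other than genotype, such as the time since stimulation, cannot be told apart from the knockout with 1 library per genotype. Further libraries of each genotype would decide whether genotype is the cause.

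Prf1 and Gzmc were lower while Gzmd, Gzme, Gzmf and Gzmg were higher, and 11.8% of the wild-type UMIs of the lower pair lay outside cluster 4, which held a smaller share of knockout cells, so that share may be part of the cause. Had that share been the whole cause with no RNA leaking between cells, the interval outside cluster 4 should have held 1. The joint ratio there was 0.527 (0.327 to 0.816 over resampled cells). This does not exclude the share as the whole cause, since Prf1 and Gzmc helped to define cluster 4 and like cells may lie in other clusters. Doublets also remain, and resampled cells carry no spread between libraries. With leaked RNA, which would lower the level outside too, the question stays open as well, as the ratio inside cluster 4 was 0.648 (0.397 to 0.997). Gzmc shares 56 stretches of 50 bases with the 4 others within the last 1000 bases, which met the bound written beforehand for shared reads, yet 0 were with Gzmf and reads from a lower Gzmc would not raise the others. Their higher level rested on few cells, as 2 knockout cells held 55.5% of the UMIs, and no genotype effect on these 4 genes can be read from it.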
